A study of Mus musculus with 10 samples.

How the data were processed

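Gene expression was measured by Smart-seq2 RNA sequencing in 10 mouse samples of sorted colon Tregs, 5 labelled Tumor and 5 labelled WT, and the group and replicate number of each sample came from its title in the labels. The deposited values were raw read counts per gene, whole numbers not normalized, for 54532 genes with names, coordinates, lengths and biotypes. Per the submitters' processing notes the genome build was mm10 and the tools named were HISAT2 2.0.5 and featureCounts 1.5.0-p3. The annotation release, the strand setting and the treatment of reads that map to several genes were not given in the sources used here. Per the labels' protocols, libraries were made from sorted cells with a transposase-based kit. Reads from a gene and an overlapping or antisense neighbour cannot be told apart where strand is not counted, and genes with near-identical copies (Bcl2a1d, Ctla2a, Ces1f, Olfr401, Vmn1r202, the hemoglobin genes) are uncertain for the same reason. The 10 single-sample count files held the same values as the deposited table of the series, which was used throughout. Of the gene identifiers, 54495 were present in GENCODE M21, 53548 with the same coordinates, and coordinates are given as the deposited table gives them (mm10). Of 557 gene names in the lists 3 were absent from the table.

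Total counts per library were 3901829, 3054435, 7747699, 5793645 and 3996988 in Tumor replicates 1 to 5 and 5719348, 8412887, 1676229, 2700019 and 1736738 in WT replicates 1 to 5. The reads carry no molecular identifiers, so amplification copies count as reads and counting error understates the error of a single library. No pair of the 45 library pairs agreed within sampling noise (smallest chi-square per degree of freedom 29.8), so all 10 counted as separate samples.

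The comparison was run in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with its defaults (minimum count 10, minimum total 15), which left 21414, and library sizes were scaled by TMM. A quasi-likelihood F test (robust, 2-sided, group as the only term) was followed by Benjamini-Hochberg adjustment over all genes tested, and genes with an adjusted p below 0.05 were called. The common dispersion was 0.742, a biological coefficient of variation of 86.1%. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic, and CPM values are TMM scaled except the library totals of marker genes, which use the total count. The procedure was tested on simulated counts for this comparison over 21414 genes. In these 200 genes were changed, a further list of genes was raised 4-fold, and 21194 genes were unchanged. Among the 200 it called 0% of genes changed 2-fold, 2.99% of those changed 4-fold and 59.1% of those changed 16-fold. Of its 42 calls, 2.38% were unchanged genes. On the same simulated counts DESeq2 called 1.49%, 32.8% and 86.4%, with 26.1% of 115 calls false, and limma voom 0%, 1.49% and 45.5%. A gene that was not called can therefore differ several fold. In the simulated counts both groups had the same dispersion, and no library was given RNA of other cells. The shares of false calls may thus differ in these libraries.

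Before the data were examined, 39 gene lists were fixed: 1 of sort markers, lists of Treg states, T cell function, metabolism and stress, 3 of library quality, and 14 of other cell types that the tissue or gate could hold. Lists with 3 or more tested genes (38) were tested with camera in limma 3.58.1 on log2 CPM, 2-sided, with a preset correlation of 0.01 and adjustment over the 38 lists, and beside it with an estimated correlation and with fry. On the simulated counts camera passed a list of raised genes and did not pass an unchanged list. Those counts were drawn independently for each gene, so false passes of correlated lists were not checked. The rule for named genes, also fixed then, took the sort markers, Apc and the Treg core genes, the 10 largest rises and 10 largest falls among called protein coding genes with a mean of at least 10 CPM and no overlap between groups (leaving out predicted, clone-named and immunoglobulin or T cell receptor segment genes), up to 3 called genes with the smallest p per list, the 2 most abundant genes of a list without calls, and the 5 genes with the smallest p, with the option to leave out genes of lists that are only counted. The test, the 25 alternatives for the gene counts and those for the lists were fixed at the same time: RLE, upper-quartile and no composition factors, DESeq2 1.42.0, limma voom without and with sample quality weights, no filter, a filter of 10 CPM in 5 libraries, a log2 fold change above 1, a test against a log2 fold change of 1, an adjusted p below 0.01, the replicate number as a block, 1 surrogate variable from sva 3.50.0, protein coding genes alone, mitochondrial, ribosomal protein and receptor segment genes left out, and each library left out in turn.

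After the data were seen, 8 alternatives for the gene counts were added: WT replicates 1 and 2, WT replicates 3 and 5, or WT replicates 3, 4 and 5 left out, scaling to 14 pan-T genes, 9 repeat-like and ribosomal RNA genes left out, subtraction of a background proportional to gene length, thinning to the smallest library, and thinning with pan-T scaling. The background rate of a library was its count per kilobase over 1466 olfactory and vomeronasal receptor genes. Pan-T scaling divides each library by the geometric mean CPM of its pan-T genes, so it expresses other genes relative to T cell RNA, and its adjusted p lies close to the unadjusted p because most genes are then called lower. A second list of 12 myeloid genes (Tyrobp, Fcer1g, Ctss, Lgmn, Cybb, Mpeg1, Sirpa, Spi1, Ms4a6c, Cd63, Trem2 and Fcgr4), sharing none with the first, was added as well. Measures of a library were compared between groups by exact permutation tests, 2-sided, with adjustment over 15 measures. Single libraries standing apart from their group were looked for with Dixon's ratio at the 95% level, on log2 values (CPM + 1 for genes). For the counts of called genes and lists, 100 of the 126 splits of the 10 libraries into 5 and 5 were fitted, the real one included.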

Results

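Regulatory T cells (Tregs), the CD4 T cells that express the transcription factor Foxp3 and restrain immune responses, were profiled by Smart-seq2, a full-length cDNA method for low RNA input. Cells positive for CD45, CD3, CD4, CD25 and GFP had been sorted from colon tumours of Apc Min/+ mice on the Foxp3 DTR background (Tumor) or from the colon of Foxp3 DTR mice (WT). Apc Min/+ mice carry a truncating allele of Apc, an inhibitor of Wnt signalling, and form intestinal tumours. Foxp3 DTR mice express a diphtheria toxin receptor under Foxp3. Each group had 5 libraries, all from male mice aged 16 weeks on C57BL/6, per the labels. No label said whether the 5 samples of a group came from separate animals, so the p-values measure the spread between these samples. Total counts ran from 3054435 to 7747699 in Tumor and from 1676229 to 8412887 in WT, and the group totals were not distinguishable (exact permutation test, 2-sided, n = 5 per group, p = 0.603).

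The Tumor libraries resembled each other more than the WT libraries did. Spearman correlations of log2 CPM (counts scaled to a common library total), across genes, were 0.64 to 0.79 among the 10 Tumor pairs (median 0.70) and 0.30 to 0.84 among the 10 WT pairs (median 0.42). T cell genes separated the groups. The 14 genes termed pan-T here include Cd3d, Cd3e, Cd3g, Cd2, Cd5, Lck, Zap70 and Cd4, the last marking the sorted lineage and not all T cells. Their geometric mean was 308 ± 55.7 CPM (SD, n = 5) in Tumor and 52.9 ± 38.3 CPM in WT. Every Tumor library lay above every WT library (exact permutation test, p = 0.00794, the smallest that 5 against 5 can give, and 0.119 after adjustment over 15 library measures). Other RNA in the WT libraries differed between replicates. WT replicates 1 and 2 held 23556 and 33355 summed CPM of 16 epithelial genes, against 156 to 327 in WT replicates 3 to 5 and 40.3 to 4941 in Tumor. In WT replicates 3, 4 and 5, 9.92%, 22.3% and 26.5% of all counts fell on Gm10800, a gene model made of repeats, against 0.844 to 5.77% in the other 7 libraries. Counts over 1466 olfactory and vomeronasal receptor genes, which T cells are not known to use, came to 5.32, 2.33 and 4.38 CPM per kilobase there and 0.837 to 2.20 in the other 7. Plasma cell genes summed to 17362 CPM in WT replicate 3, and 12 macrophage and monocyte genes to 1334 to 6063 CPM in Tumor against 74.7 to 212 in WT. Fold changes are given on the fixed scaling (trimmed mean of M values, TMM), and the value with each library scaled to its pan-T genes, a scaling chosen after the data were seen, is given in the same paragraph. Of the 293 genes called higher on TMM, 21 were also called higher with pan-T scaling, where the adjusted p lies close to the unadjusted p because most genes are then called lower.

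**Figure D1:**
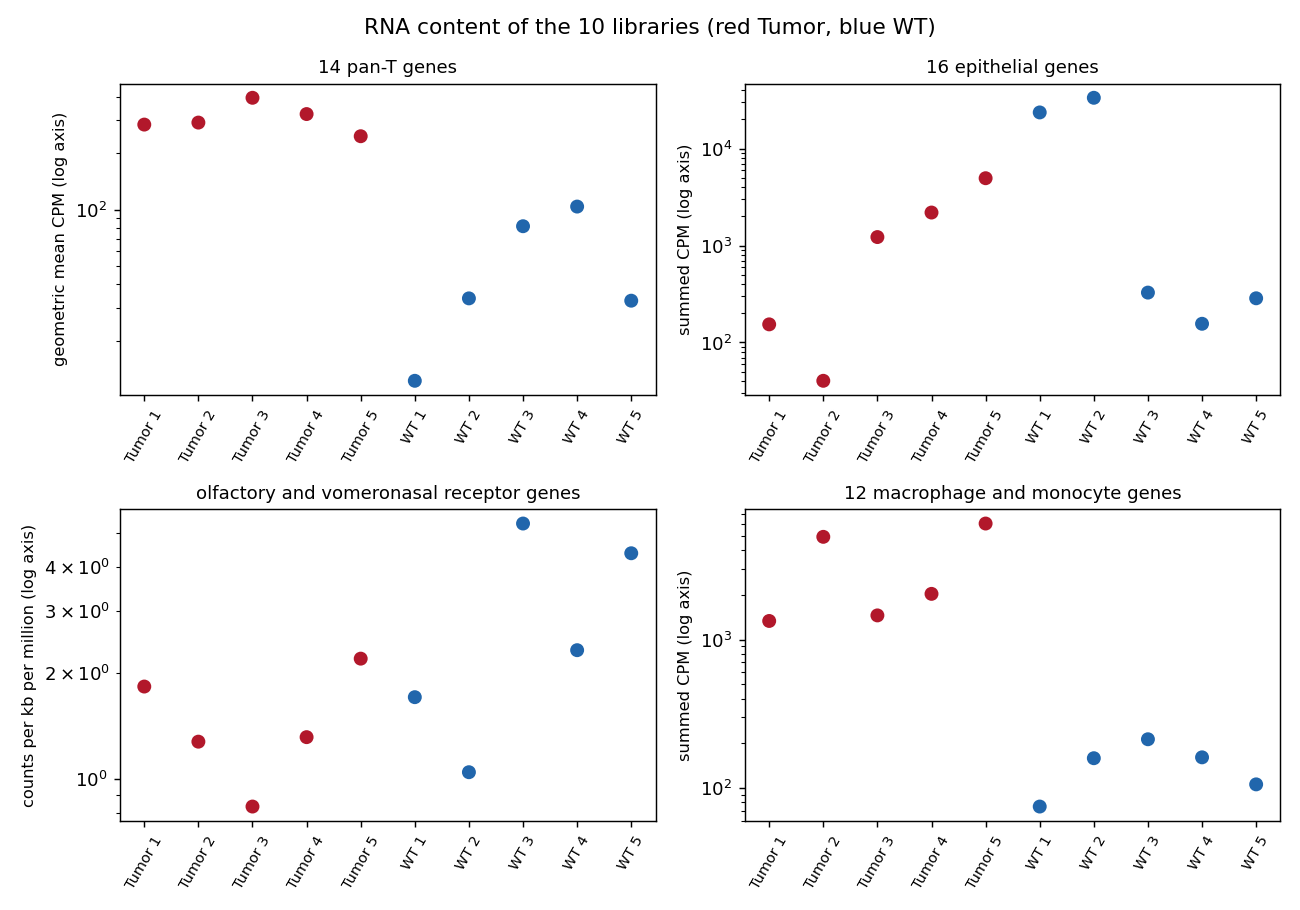
Content of the 10 libraries, each point a library (red Tumor, blue WT, n = 5 each): geometric mean CPM of 14 pan-T genes, summed CPM of 16 epithelial genes, CPM per kilobase over olfactory and vomeronasal receptor genes, and summed CPM of 12 macrophage and monocyte genes, all on log axes. All 5 Tumor libraries lie above all 5 WT libraries for the pan-T and the macrophage genes, and WT replicates 1 and 2 stand highest for the epithelial genes.

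The comparison of Tumor with WT asks how Tregs of Apc Min/+ colon tumours differ in gene expression from Tregs of colon without that allele. The genes furthest above WT included receptors of activated Tregs. Ccr8, a chemokine receptor (ENSMUSG00000042262, chromosome 9, 120092114 to 120094906), stood at 167 ± 85.7 CPM (SD, n = 5) in Tumor and 2.03 ± 2.12 in WT, a log2 fold change of 6.31 ± 0.94 (SE, adjusted p = 0.00566). Tnfrsf9, the costimulatory receptor 4-1BB (ENSMUSG00000028965, chromosome 4, 150914562 to 150946102), stood at 1531 ± 493 and 27.9 ± 33.0 CPM, with a log2 fold change of 5.78 ± 0.95 (adjusted p = 0.00612). Among the genes eligible under the naming rule (called, protein coding, at least 10 CPM on average, no overlap between groups), the widest rise was that of Penk. It encodes the opioid peptide precursor proenkephalin (ENSMUSG00000045573, chromosome 4, 4133531 to 4138819) and rose from 7.52 ± 9.88 to 1552 ± 607 CPM, a log2 fold change of 7.67 ± 1.21 (adjusted p = 0.00566). All 5 Tumor libraries lay above all 5 WT libraries for each of these genes, and each stayed higher after pan-T scaling, by 3.42 ± 1.02, 3.13 ± 0.94 and 5.16 ± 1.13 log2 units (SE). In all, 340 of 21414 tested genes differed (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05), 293 higher and 47 lower in Tumor, and in 319 of them the groups did not overlap. Complete separation held for 1273 of the tested genes, or 5.94%, where chance gives 0.794%. The count of 340 became 127, 81, 65, 107 and 214 without Tumor replicates 1 to 5 in turn and 69 without WT replicate 1. It rose to 1993 without WT replicates 1 and 2 and to 1325 without WT replicates 3, 4 and 5, sets chosen after the data were seen. DESeq2 called 682 higher and 969 lower, and with a length-proportional background subtracted, also chosen afterwards, edgeR called 0 (732 at an unadjusted p below 0.05). After pan-T scaling 23 genes were higher and 18933 lower, so the 86.2% share of higher calls depends on the scaling, and the median log2 fold change of all tested genes moved from -0.20 to -3.46.

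Among the other genes with the largest rises, Il17a, a cytokine of T helper 17 and innate-like T cells (ENSMUSG00000025929, chromosome 1, 20730905 to 20734496), had 49 to 1201 reads per Tumor library and 0 to 5 per WT library, a log2 fold change of 7.25 ± 0.93 (adjusted p = 0.00341). Apoe, a lipid carrier made by macrophages, and Lyz2, a lysozyme of myeloid cells, rose by 6.65 ± 1.28 and 5.76 ± 1.01 log2 units (SE, adjusted p = 0.0153 and 0.00842). Ctla2a, a cysteine protease inhibitor, and Cst7, which encodes cystatin F, rose by 5.70 ± 0.87 and 5.64 ± 0.74 (adjusted p = 0.00566 and 0.00341). These 5 genes also stayed higher after pan-T scaling, Cst7 least, by 2.29 ± 0.93 (adjusted p = 0.0251). Rln3, a relaxin peptide, and Tff1, a trefoil peptide of mucosal epithelium, had log2 fold changes of 5.95 ± 1.11 and 5.68 ± 1.21 (adjusted p = 0.0121 and 0.0261) on TMM and did not pass after pan-T scaling (1.84 ± 1.30 and 1.80 ± 1.19, adjusted p = 0.175 and 0.148). Tff1 was no longer called without some single libraries, its adjusted p reaching 0.109. The 5 genes with the smallest p were Il17a, Cst7, the interferon-induced GTPase gene Ifi47 (4.27 ± 0.58), the predicted gene Gm5547 (5.47 ± 0.76) and the matrix metalloproteinase gene Mmp9 (4.50 ± 0.63), each with adjusted p = 0.00341. Ifi47, Gm5547 and Mmp9 had positive values that did not pass after pan-T scaling (0.89 ± 0.82, 2.16 ± 1.11 and 1.31 ± 0.87).

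Genes of the sort markers were higher in Tumor as a list. Of the 7 sort marker genes, 3 rose, the T cell receptor complex genes Cd3g (3.78 ± 0.73, adjusted p = 0.0153) and Cd3d (3.25 ± 0.80, 0.0460) and the IL-2 receptor gene Il2ra (3.30 ± 0.81, 0.0436), and 7 passed when adjusted over the list alone. Foxp3 (ENSMUSG00000039521, chromosome X, 7579676 to 7595243) was at 92.2 ± 40.4 CPM in Tumor and 16.6 ± 14.97 in WT, a log2 fold change of 2.48 ± 0.64 that did not pass (adjusted p = 0.0560). Cd4 (2.63 ± 0.71, adjusted p = 0.0697), Cd3e (2.15 ± 0.62, 0.0895) and Ptprc (2.21 ± 0.76, 0.158) did not pass either. The list had a median log2 fold change of 2.63 and camera adjusted p = 9.23e-10, against adjusted p = 0.0618 with an estimated correlation, and its median was -0.024 after pan-T scaling, which uses 4 of its 7 genes. Of 16 Treg core genes, 6 rose: Capg, an actin-capping protein gene (3.66 ± 0.73), Itgae, the integrin CD103 (2.68 ± 0.57), Il2rb (3.48 ± 0.78), Tnfrsf18, the receptor GITR (3.91 ± 0.88), Ikzf4 (2.17 ± 0.52) and Il2ra, with adjusted p from 0.0162 to 0.0436. The list alone gave 13 calls. Ctla4, an inhibitory receptor, had a log2 fold change of 3.86 ± 0.98 and did not pass (adjusted p = 0.0516). Ebi3, Nrp1, Izumo1r, Ikzf2, Socs2, Cd83, Lrrc32 and Gpr83 did not pass, with values from 0.24 ± 0.91 for Gpr83 to 2.94 ± 0.82 for Ebi3. The Treg core list had a median log2 fold change of 2.32 and camera adjusted p = 1.38e-13, against adjusted p = 0.0618 with an estimated correlation, and after pan-T scaling its median turned to -0.79, with 0 of the 16 genes called higher (0 at an unadjusted p below 0.05) and 3 (Socs2, Lrrc32 and Gpr83) called lower. None of the called sort marker and Treg core genes passed after pan-T scaling: Cd3g 0.85 ± 0.78, Cd3d 0.65 ± 0.87, Il2ra 0.81 ± 0.73, Capg 0.54 ± 0.91, Itgae -0.69 ± 0.71, Il2rb 0.78 ± 0.77, Tnfrsf18 1.30 ± 0.81 and Ikzf4 -0.98 ± 0.73 (log2 units, SE). The calls of Ikzf4, Il2ra, Cd3d and Cd3g held in 1, 2, 2 and 7 of the 10 fits that left out 1 library, while their log2 fold changes stayed at 2.01 to 2.63, 2.96 to 4.17, 2.96 to 3.72 and 3.53 to 3.99. Those of Tnfrsf18, Itgae, Il2rb and Capg held in 4, 5, 5 and 6 of these fits.

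Effector Treg activation genes, fixed beforehand as markers of activated tissue Tregs, rose in 10 of 22 cases and passed in 22 of 22 when adjusted over the list alone. The list had a median log2 fold change of 2.83 and camera adjusted p = 1.07e-25, against adjusted p = 0.0586 with an estimated correlation. Besides Ccr8 and Tnfrsf9, the inhibitory receptor gene Pdcd1 rose by 5.27 ± 0.90 (adjusted p = 0.00728), from 7.71 ± 8.72 to 300.1 ± 72.7 CPM. After pan-T scaling the list median was 0.24, and 5 of its genes stayed called higher: Ccr8, Tnfrsf9, Pdcd1 (2.43 ± 0.84, adjusted p = 0.0111), the receptor gene Klrg1 (2.33 ± 0.73, 0.00661) and the chemokine receptor gene Cxcr6 (2.001 ± 0.74, 0.0161), the last named after its values were seen. Of 15 suppressive mediators 5 rose, with the list alone 12. This list had a median log2 fold change of 2.36 and camera adjusted p = 4.24e-12, against adjusted p = 0.0586 with an estimated correlation. The rises included Lgals1, encoding galectin-1 (4.36 ± 0.84, adjusted p = 0.0153), the granzyme gene Gzma (4.91 ± 0.996, 0.0186) and Areg, encoding the growth factor amphiregulin (3.97 ± 0.93, 0.0363). After pan-T scaling the list median turned to -0.82, Gzma stayed higher (1.98 ± 0.87), and Lgals1 (1.75 ± 0.91) and Areg (0.70 ± 0.999) did not pass. Lists for colonic Treg subtypes passed as well, and no test compared them with each other. Of 12 RORgt-type Treg genes 3 rose, Cxcr3, Prdm1 and Ccr6 (4.01 ± 0.75, 2.92 ± 0.57 and 3.38 ± 0.71), and 9 with the list alone. Their list had a median log2 fold change of 2.46 and camera adjusted p = 3.49e-10, against adjusted p = 0.0648 with an estimated correlation. Of 12 Gata3-type Treg genes 4 rose, among them Bcl2a1d, an anti-apoptotic BCL2 relative, Klrg1 and Gata3 (4.73 ± 0.72, 4.98 ± 0.89 and 3.33 ± 0.74), and with the list alone 11 were higher and 1 lower. Here the list had a median log2 fold change of 2.54 and camera adjusted p = 1.83e-11, against adjusted p = 0.0618 with an estimated correlation. The pan-T scaled medians of these lists were -0.28 and -0.015. Bcl2a1d and Klrg1 stayed higher under that scaling, Bcl2a1d by 1.98 ± 0.84, whereas Cxcr3 1.26 ± 1.01, Prdm1 -0.31 ± 0.75, Ccr6 0.25 ± 0.87 and Gata3 0.79 ± 0.68 did not pass. The pan-T genes themselves, measured in the same libraries, had a median log2 fold change of 2.83.

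**Figure D2:**
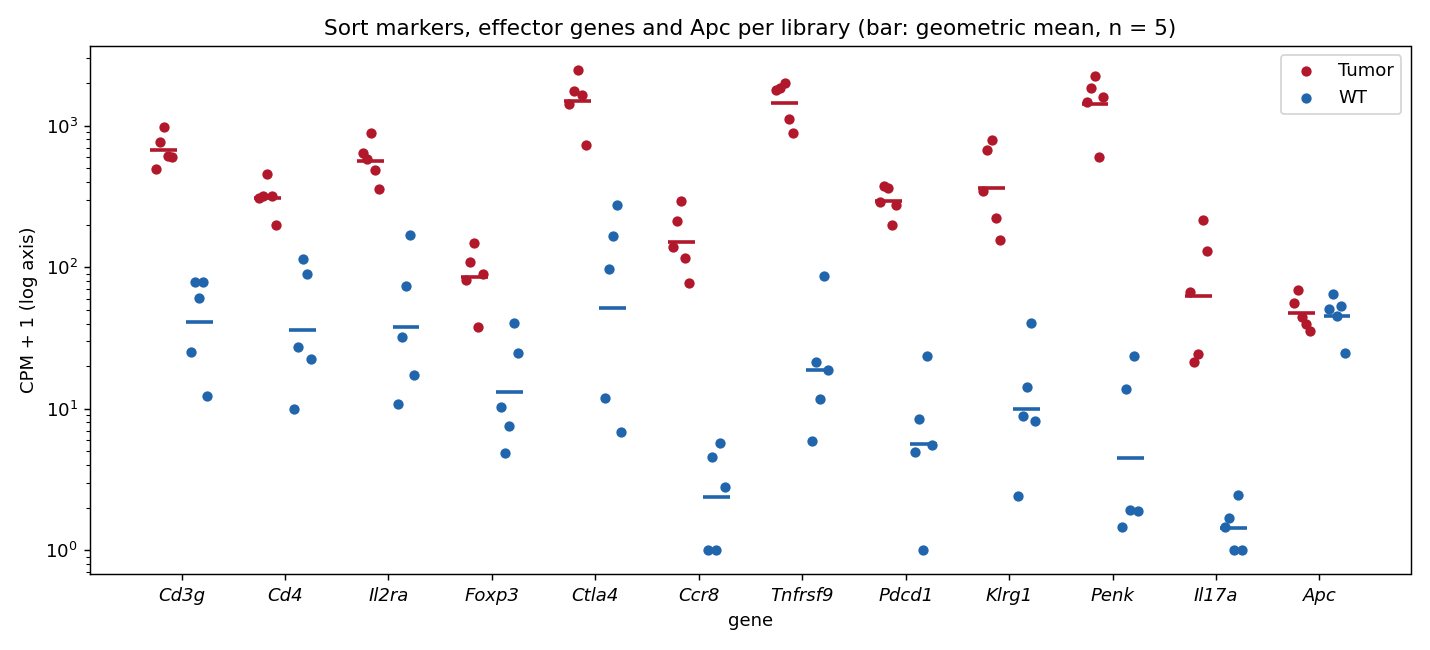
CPM + 1 on a log axis for sort markers, effector genes and Apc in each library (red Tumor, blue WT, n = 5 each), with a bar at the geometric mean. Tumor and WT points do not overlap except for Foxp3, where 1 WT library reaches into the Tumor range, and for Apc, where the groups lie together.

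Genes of cell positioning and contact were also higher in Tumor. Of 23 tested chemokine receptor and homing genes 12 rose and 20 passed with the list alone, among them Ccr8, Ccr1 (4.60 ± 0.75, adjusted p = 0.00612) and the oxysterol receptor gene Gpr183 (3.74 ± 0.66, 0.00842). As a list they had a median log2 fold change of 2.68 and camera adjusted p = 2.44e-20, against adjusted p = 0.0618 with an estimated correlation. The study's title concerns contact between Tregs and mature regulatory dendritic cells. Of 20 genes for contact with dendritic cells 7 rose and 16 passed with the list alone. The list had a median log2 fold change of 2.81 and camera adjusted p = 8.89e-16, against adjusted p = 0.0618 with an estimated correlation. The rises included the checkpoint receptor gene Tigit (3.94 ± 0.69, adjusted p = 0.00842), Ltb, encoding lymphotoxin beta (3.90 ± 0.71, 0.0102), and Tnfsf11, encoding RANKL (2.90 ± 0.56, 0.0153). The medians of both lists turned negative after pan-T scaling (-0.20 and -0.21), where Ccr8 stayed higher and Ccr1 1.53 ± 0.81, Gpr183 0.89 ± 0.67, Tigit 0.76 ± 0.72, Ltb 0.89 ± 0.72 and Tnfsf11 0.12 ± 0.82 did not pass. The contact list includes Cd2 and Cd5, which the scaling itself uses. Its TMM median of 2.81 is near that of the pan-T genes (2.83). Of 14 naive and central memory genes 2 rose, the IL-7 receptor gene Il7r (4.21 ± 0.85, adjusted p = 0.0186) and the transcription factor gene Klf2 (2.76 ± 0.59, 0.0242), and 3 with the list alone. Together they had a median log2 fold change of 1.12 and camera adjusted p = 0.000467, against adjusted p = 0.198 with an estimated correlation. Of 19 early T cell receptor response genes 2 rose, Dusp2 (3.51 ± 0.60, adjusted p = 0.00744) and Cd69 (3.09 ± 0.72, 0.0343), and 6 with the list alone. This list had a median log2 fold change of 1.62 and camera adjusted p = 2.02e-10, against adjusted p = 0.0779 with an estimated correlation. Of 8 tested helper T cytokine genes Il17a alone rose, and 2 with the list alone. Their list had a median log2 fold change of 0.87 and camera adjusted p = 0.0201, against adjusted p = 0.198 with an estimated correlation. Pan-T scaled medians of these 3 lists were -1.87, -1.77 and -2.35. Il17a stayed higher under that scaling, and Il7r 1.61 ± 0.82, Klf2 -0.35 ± 0.72, Dusp2 0.46 ± 0.72 and Cd69 -0.0043 ± 0.77 did not pass.

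Metabolic and stress lists gave few called genes. Slc16a3, a lactate exporter, was the call among 17 glycolysis genes (2.38 ± 0.51, adjusted p = 0.0227). The glycolysis list had a median log2 fold change of 0.93 and camera adjusted p = 1.47e-06, against adjusted p = 0.198 with an estimated correlation. Ddit4 and Hilpda, both induced by low oxygen, rose among 17 tested hypoxia genes (3.66 ± 0.60 and 4.58 ± 0.86, adjusted p = 0.00612 and 0.0131). The hypoxia list had a median log2 fold change of 1.25 and camera adjusted p = 7.18e-05, against adjusted p = 0.198 with an estimated correlation. Among 19 lipid uptake and oxidation genes Fabp5, a fatty acid binding protein, rose (5.28 ± 0.76, adjusted p = 0.00395) and stayed higher after pan-T scaling (1.90 ± 0.77). The lipid list did not pass (camera adjusted p = 0.765, direction up against a median of -0.67). Of 22 interferon response genes 3 rose, among them the GTPase gene Igtp (3.54 ± 0.65, adjusted p = 0.0106), and the list did not pass (median 0.31, camera adjusted p = 0.0725) on all libraries and passed upward without Tumor replicate 1 or 5 or WT replicate 3 or 4 (0.0294, 0.0174, 0.0447 and 0.0481) and with the stricter filter (0.0398). With an estimated correlation these 5 passes were lost (adjusted p = 0.253 to 0.451). With list alone adjustment these 4 lists gave 1, 4, 2 and 6 higher calls. Cd74, the invariant chain, was the call among 9 tested class II presentation genes (3.66 ± 0.81, adjusted p = 0.0283), with 6 calls for the list alone. As a list these had a median log2 fold change of 2.47 and camera adjusted p = 9.07e-07, against adjusted p = 0.0779 with an estimated correlation. No gene was called in 6 further lists of metabolism, growth and stress. Proliferation had a median log2 fold change of 0.43 and camera adjusted p = 0.00946, against adjusted p = 0.355 with an estimated correlation, with 2 of 28 genes higher for the list alone. Cytosolic ribosomal proteins had a median log2 fold change of 0.87 and camera adjusted p = 2.88e-11, against adjusted p = 0.398 with an estimated correlation. The unfolded protein response had a median log2 fold change of 0.82 and camera adjusted p = 1.998e-05, against adjusted p = 0.344 with an estimated correlation. Both had 0 calls for the list alone. Heat shock genes, a sign of tissue dissociation, had a median log2 fold change of 1.28 and camera adjusted p = 6.00e-05, against adjusted p = 0.104 with an estimated correlation, also with 0. Oxidative phosphorylation passed upward (camera adjusted p = 0.000421, and 0.568 as adjusted p with an estimated correlation) although its median was -0.34 and its mean -0.30. Its direction depends on the WT libraries kept: without WT replicates 3, 4 and 5 it passed downward (median -1.54, adjusted p = 1.44e-10), without WT replicates 1 and 2 upward (median 2.64, adjusted p = 3.59e-18), and without WT replicate 5 it did not pass (adjusted p = 0.0695). The 2 passes were lost in the same fits, with adjusted p = 0.172 and 0.152 with an estimated correlation. The summed CPM of its genes was 13177 and 18782 in WT replicates 1 and 2, 541 to 1929 in WT replicates 3 to 5 and 4839.5 to 7679 in Tumor. Cholesterol synthesis did not pass (median -0.67, camera adjusted p = 0.552). Wnt target genes did not pass (median 0.31, camera adjusted p = 0.554, 0 of 11 called). Apc (ENSMUSG00000005871, chromosome 18, 34220924 to 34322189) stood at 47.6 ± 13.5 CPM in Tumor and 46.6 ± 14.7 in WT, a log2 fold change of 0.029 ± 0.46 (adjusted p = 0.983). Apc CPM was 54.8, 67.5, 43.2, 38.5 and 34.2 in Tumor replicates 1 to 5 and 49.8, 63.4, 44.1, 52.0 and 23.6 in WT. A count over the whole gene does not read the Min allele. Apc is also long (15753 bases). Background at the receptor-gene rates of WT replicates 3 and 5 (5.32 and 4.38 CPM per kilobase) would alone exceed its level there. The close group means therefore do not show equal Apc RNA. After pan-T scaling Slc16a3 -0.79 ± 0.83, Ddit4 0.36 ± 0.93, Hilpda 1.25 ± 0.84, Igtp 0.43 ± 0.72 and Cd74 1.003 ± 0.82 did not pass. All of these list medians were negative there, from -4.24 for lipid uptake to -0.96 for class II presentation.

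In total 21 of 38 lists passed the set test, all upward, and 0 passed with an estimated correlation, where 12 had an unadjusted p below 0.05 and fry, a self-contained test, passed 17. With an estimated correlation 10 lists passed without WT replicate 4 (smallest adjusted p = 0.0201), the macrophage list alone without Tumor replicate 3 (0.0498) or 5 (0.0298), and 9 with pan-T scaling, where the test compares a list with the other genes and 8 of those 9 medians were below 0. All 21 kept their direction in the fits without 1 library, except that helper T cytokines did not pass without WT replicate 2 nor oxidative phosphorylation without WT replicate 5. Without WT replicates 3, 4 and 5, 17 lists passed upward and 4 downward (oxidative phosphorylation, cholesterol synthesis, mitochondrially encoded and epithelial genes), and glycolysis, proliferation, ribosomal proteins and the unfolded protein response did not pass. In that fit 0 lists passed with an estimated correlation (smallest adjusted p = 0.0554, and fry passed 16). The 21 lists include 2 of other cell types. Macrophage and monocyte genes rose in 5 of 11 tested cases, 8 with the list alone, among them the complement genes C1qa and C1qb (5.61 ± 0.89 and 5.03 ± 0.78, adjusted p = 0.00573 and 0.00566), Lyz2 and Apoe. The list had a median log2 fold change of 2.48 and camera adjusted p = 5.08e-10, against adjusted p = 0.0586 with an estimated correlation. These 4 genes stayed higher after pan-T scaling, with C1qb least at 2.30 ± 0.86, while the list median turned to -0.70. Il1b was the call among 8 neutrophil genes (4.46 ± 0.95, adjusted p = 0.0226). The neutrophil list had a median log2 fold change of 1.66 and camera adjusted p = 0.00625, against adjusted p = 0.297 with an estimated correlation, and its pan-T scaled median was -1.36. Epithelial genes had 0 of 16 called, a median of -2.50 and camera adjusted p = 0.118. Their most abundant members Krt8 and Lgals4 had log2 fold changes of -2.57 ± 1.81 and -2.72 ± 1.74, which turned to 4.72 and 5.35 without WT replicates 1 and 2, as did the list median, to 2.45, and the list then passed upward (adjusted p = 0.0391), as did the mitochondrially encoded genes (0.00553). The epithelial list passed downward without Tumor replicate 5 or WT replicate 3, 4 or 5 (adjusted p = 0.0366, 0.0150, 0.00904 and 0.0254), and also without WT replicates 3 and 5, without WT replicates 3, 4 and 5, and with the stricter filter. None of these passes, upward or downward, held with an estimated correlation (adjusted p = 0.192 to 0.653 for the epithelial and 0.400 for the mitochondrially encoded list). Cd8 T and NK cell genes gave 2 calls of 10, among them Nkg7 (3.95 ± 0.88, adjusted p = 0.0292), and did not pass as a list (median 0.33, camera adjusted p = 0.295). Genes of mature regulatory dendritic cells gave 1 call of 10, Pdcd1lg2 (3.76 ± 0.64, adjusted p = 0.00728), and did not pass (median 0.97, camera adjusted p = 0.0605) on all libraries and passed upward without Tumor replicate 5, WT replicate 3 or WT replicate 5 (0.0429, 0.0185 and 0.0358). They also passed upward without WT replicates 3 and 5, without WT replicates 3, 4 and 5, and against the other genes with pan-T scaling (0.0115, 0.00260 and 0.000610), where their median was -1.99. None of these 6 passes held with an estimated correlation (adjusted p = 0.0934 to 0.229). After pan-T scaling Il1b 1.36 ± 0.91, Nkg7 0.66 ± 0.94 and Pdcd1lg2 0.41 ± 0.98 did not pass. Il17a was the call among 5 tested gamma delta T and innate lymphoid genes (median 0.14, camera adjusted p = 0.247). No gene was called, and the list did not pass, for B cells (median -0.98), plasma cells (-1.97), dendritic cells (0.39), mast cells and basophils (-1.17), fibroblasts (-0.22), endothelium (-0.62), enteric glia and neurons (-0.83), mitochondrially encoded genes (-1.47) and sex-linked genes (-0.36), with camera adjusted p from 0.181 to 0.907. Only 2 erythroid genes were tested, neither called, too few for the set test.

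**Figure D3:**
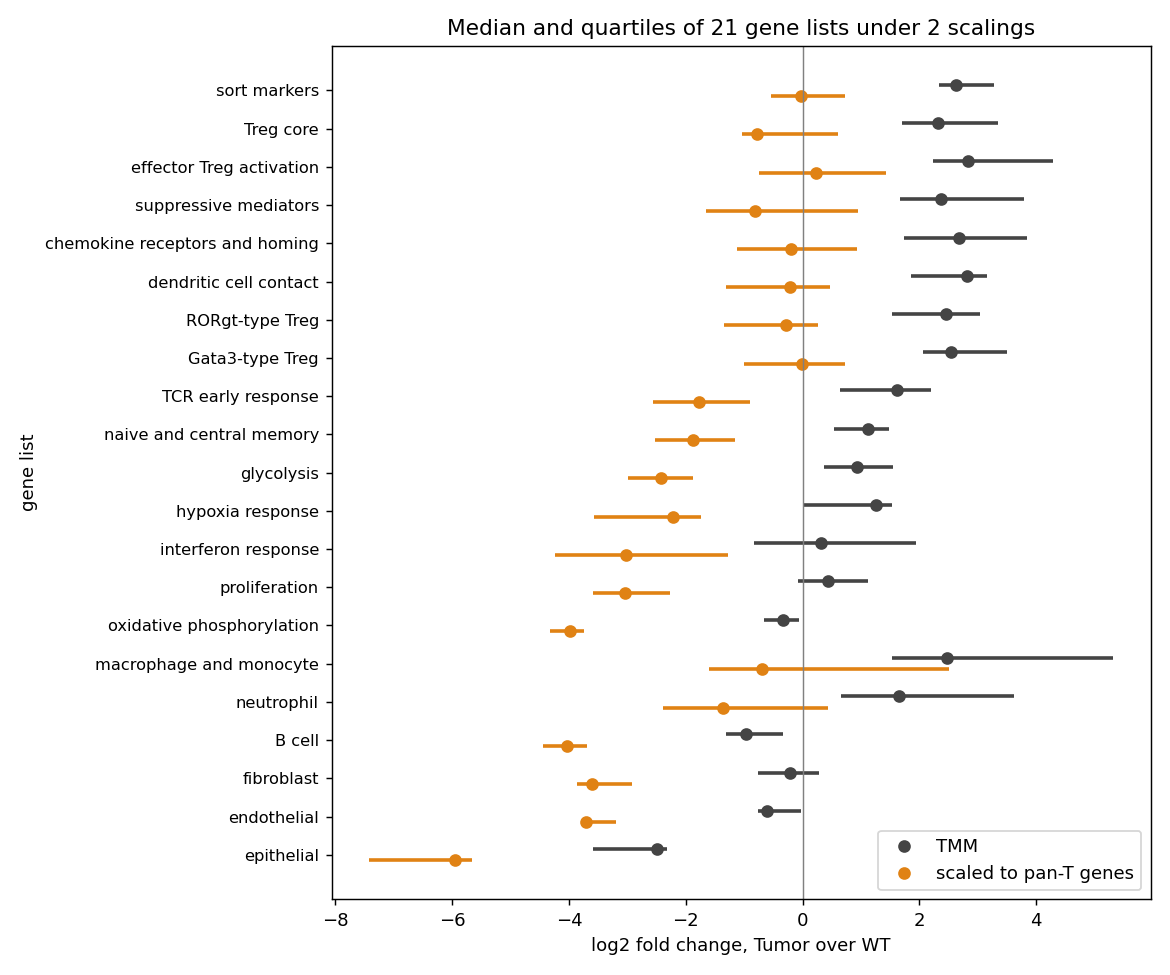
Median (point) and quartiles (line) of the log2 fold change, Tumor over WT, over the tested genes of 21 of the fixed lists, on TMM scaling (grey) and with libraries scaled to 14 pan-T genes (orange). Medians of the Treg core, effector, suppressive mediator, RORgt-type and Gata3-type lists lie above 0 on TMM and between -1 and 1 after pan-T scaling. So do those of the sort marker, chemokine receptor, dendritic cell contact and macrophage lists. After pan-T scaling only the effector median (0.24) lies above 0, with naive and central memory at -1.87. The epithelial median lies below 0 on both.

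No gene of the fixed lists was among the 47 called lower in Tumor. The 47 genes were not assigned to a source as a group. Olfr401 and Vmn1r202, named below, belong to the 1466 receptor genes used as the measure of background, so their WT reads count as background there. Among the genes eligible under the naming rule, the largest fall was that of Mptx1, a mucosal pentraxin of intestinal epithelium (ENSMUSG00000026531, chromosome 1, 174330518 to 174332873). It had 46021 and 74690 reads in WT replicates 1 and 2, 15 to 105 in WT replicates 3 to 5, 12 in Tumor replicate 2 and 0 in the other Tumor libraries. Its log2 fold change of -12.25 ± 2.75 (adjusted p = 0.0380) rests on those extremes and was called in 3 of the 10 fits that left out 1 library. The other 9 largest falls were of Lrrn4 (-4.86 ± 0.99), the olfactory receptor gene Olfr401 (-4.84 ± 1.09), the casein gene Csn1s2a (-4.31 ± 0.89), the GMP reductase gene Gmpr (-4.30 ± 0.93), the chloride channel gene Clic5 (-4.28 ± 0.83), the vomeronasal receptor gene Vmn1r202 (-4.02 ± 0.94), the ectonucleotidase gene Entpd8 (-4.00 ± 0.91), the carboxylesterase gene Ces1f (-3.70 ± 0.83) and Nxpe4 (-3.52 ± 0.82), with adjusted p from 0.0153 to 0.0357. Their Tumor means were 0.749 to 5.21 CPM. By reads, WT replicates 1 and 2, the deepest WT libraries, held most of the WT reads of Clic5, Entpd8, Ces1f, Nxpe4 and Gmpr. By CPM, they were the 2 highest WT libraries for Clic5 (80.0 and 107), Entpd8 and Ces1f, while WT replicate 3 was highest for Lrrn4, Csn1s2a, Gmpr (57.7) and Vmn1r202, WT replicate 2 for Nxpe4 (48.5) and WT replicate 5 for Olfr401 (68.9). Without Tumor replicate 1, 2, 3, 4 or 5 the 47 lower calls became 7, 6, 2, 2 and 17, without WT replicate 1 they became 6, and without WT replicate 4 72.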

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

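The tests of explanations here were chosen after the results were seen, the thinning to equal pan-T reads after the pan-T scaled values though before its own result, and only the count of splits was planned. A single library stood apart from the other 4 of its group (gap to the nearest library over the range of the group) in 8 of 266 groups of values checked, where chance gives about 13.3. For list totals, sex-linked genes were high in Tumor replicate 4 (ratio 0.776, 361 CPM against 201 in the nearest library), plasma cell genes in Tumor replicate 1 (0.824, 3006 against 218) and mast cell genes in WT replicate 3 (0.738, 375 against 71.4). For single genes, Nrp1 was high in WT replicate 4 (ratio 0.760), Mptx1 had its Tumor reads in Tumor replicate 2 alone (1), Cxcr3 and Il7r were low in Tumor replicate 5 (0.733 and 0.783), and Ddit4 was low in WT replicate 5 (0.868).

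Of 100 splits of the 10 libraries, 1 gave as many as 340 called genes, the real one, with 99 the highest of the others. For genes higher it was 1 (293, highest other 96) and for genes lower 1 (47, highest other 3), so a chance split of the libraries is argued against for these counts. For the lists 9 of 100 splits gave 21 or more, with 25 the highest of the others, so for the number of lists passing chance is not excluded.

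The first pattern is that 8 of 21 sort marker and Treg core genes rose and none fell. Epithelial RNA in WT replicates 1 and 2 was examined by leaving them out, and the 14 pan-T genes kept a median log2 fold change of 2.40 (quartiles 1.79 to 2.86). Without WT replicates 3, 4 and 5, left out to examine genomic background, the median was 3.69 (3.30 to 4.01). The lower pan-T values were thus not confined to either set of WT libraries. Both outcomes were fixed beforehand, since every WT library was already seen to lie below every Tumor library for these genes. They repeat that separation and are no separate evidence on either cause. A smaller share of T cell RNA in all WT libraries, taken up by other RNA or background, stays open as a candidate explanation, since its test restates that the Treg core genes rose by no more than the pan-T genes (2.83): after pan-T scaling the Treg core median went from 2.32 (quartiles 1.71 to 3.35) to -0.79 (-1.03 to 0.60), and edgeR then called 0 of these 16 genes higher (0 at an unadjusted p below 0.05) and 3 lower, none of the 16 being a pan-T gene. Whether fewer cells were sorted, less RNA was left per cell, or Tregs of normal colon hold less of these transcripts stays open, as does the Apc genotype.

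The second pattern is the rise of effector Treg activation genes beyond the pan-T genes. A smaller share of T cell RNA in the WT libraries as the whole cause was tested by pan-T scaling, with adjustment over the list alone. Of the 22 genes 4 stayed higher, Ccr8, Tnfrsf9, Klrg1 and Pdcd1 (adjusted p = 0.0267 to 0.0402), with 0 lower. The pattern was defined by these same scaled values, so the test restates it and does not decide on that cause. Background reads in the WT pan-T genes were not removed and could enlarge the scaled folds. With background subtracted, on TMM, edgeR called 0 genes. WT reads were also few, 0 to 26 for Ccr8 and 0 to 62 for Pdcd1. Fewer T cell reads in the WT libraries were examined by thinning every library to the 988 pan-T reads of the poorest. The same 4 genes were called, Ccr8 at 3.33 ± 0.80 (SE) and Pdcd1 at 2.42 ± 0.77. Thinning keeps each gene's expected ratio to the pan-T genes, and the 4 genes were picked from the unthinned values. The outcome was thus largely fixed beforehand. It shows that these calls do not need the deeper Tumor reads. Loss of transcripts before amplification was not tested, so fewer T cell reads stay open as a cause. Cxcr6 passed after pan-T scaling when adjusted over all genes tested (0.0161) and not over the list alone (0.0518), and the other 17 genes passed upward under neither. A difference between tumour and normal colon Tregs, by genotype or tissue, remains a hypothesis for these 4 genes, and RNA of other lymphocytes in the gate was not tested.

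The third pattern is the rise of macrophage genes. A smaller share of T cell RNA in the WT libraries alone was predicted to raise markers of non-T cells in WT. The macrophage list instead had a median of 2.48 in Tumor over WT (quartiles 1.53 to 5.32). The prediction need not hold, since epithelial RNA or background in the WT libraries would lower macrophage RNA there as well. Neither this median nor that of the second myeloid list below can therefore decide on that cause. More macrophage RNA in the Tumor libraries passed its test, as the second myeloid list had a median of 2.47 (1.88 to 3.27) and 6 of 12 genes called higher, although the gate on CD3, CD4 and GFP should remove such cells and its most abundant gene, Ctss, was at 435 ± 109 CPM in Tumor and 101.03 ± 112 in WT. After pan-T scaling that list had a median of -0.69 (-1.54 to 0.31), and in the first list, adjusted over the list alone, Lyz2, Apoe, C1qa and C1qb were higher (adjusted p = 0.0174 to 0.0230) and Adgre1 and Mrc1, named after their values were seen, lower (-2.81 ± 1.003 and -2.78 ± 1.001), so a rise beyond the pan-T genes is not shown for the list as a whole. Uptake or expression of these transcripts by tumour Tregs stays open and was not tested.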

How the results depend on the processing

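Settings named here as left-out sets, pan-T scaling, thinning, repeat-like genes or background were chosen after the data were seen, and causes were not tested unless given. Called genes (higher and lower in parentheses) numbered 340 (293 and 47) as reported. They were 270 (211 and 59) with RLE factors, 291 (227 and 64) with upper-quartile factors, 269 (222 and 47) with library size alone, 1651 (682 and 969) with DESeq2, 479 (455 and 24) with limma voom, 768 (671 and 97) with quality weights added, 820 (479 and 341) with no filter, 75 (74 and 1) against a log2 fold change of 1, 772 (562 and 210) with 1 surrogate variable and 52 (52 and 0) at an adjusted p below 0.01. The stricter filter, a fold above 1, protein coding genes alone, and mitochondrial, ribosomal and receptor segment genes left out kept all 3 counts within 1.5 times. Without each library in turn, with fewer samples by construction, the counts were 65 to 417, higher 63 to 350 and lower 2 to 72, lowest for all genes without Tumor replicate 3 (65), WT replicate 1 (69) and Tumor replicate 2 (81). They were 1993 (1615 and 378) without WT replicates 1 and 2, 443 (338 and 105) without WT replicates 3 and 5, 1325 (696 and 629) without WT replicates 3, 4 and 5, 18956 (23 and 18933) with pan-T scaling, 306 (245 and 61) with thinning, 13575 (28 and 13547) with both and 302 (245 and 57) without repeat-like genes. With background subtracted edgeR called 0 (0 and 0) of 11696 genes, with 732 at an unadjusted p below 0.05, and of the 340 genes 303 were tested and all of those kept their direction. The background estimate came to 68.6% and 56.4% of the counts of WT replicates 3 and 5, so lost counts can contribute to the 0 calls. The median log2 fold change of all genes was -0.20 with TMM, -0.38 with RLE and -0.40 with library size alone.

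Replicate numbers did not pair the samples: correlations of same-numbered deviations were -0.13 to 0.038, none above 0.1, and with the replicate number as a block the calls were 141 (138 and 3). Krt8 and Lgals4 turned to 2.54 and 3.39 under the block. Of 38 lists 21 passed as reported, all upward, 0 with an estimated correlation, 17 with fry (12 to 20 over the settings) and 20 to 24 under the other settings, the block included. With an estimated correlation 9 lists passed with pan-T scaling (smallest adjusted p = 9.55e-06), 10 without WT replicate 4, 1 (macrophage) without Tumor replicate 3 or 5 and 0 under each other setting, and the changes below are those at the preset correlation. Downward were 4 of them without WT replicates 3, 4 and 5 (epithelial, cholesterol synthesis, mitochondrially encoded, and oxidative phosphorylation, which passes upward as reported), the first 3 of these without WT replicates 3 and 5, 2 with the stricter filter (epithelial and fibroblast), and the epithelial list without Tumor replicate 5 or WT replicate 3, 4 or 5. Passing upward though not as reported were the epithelial and mitochondrially encoded lists without WT replicates 1 and 2, and the CD8 T and NK cell and the gamma delta T lists with pan-T scaling. The interferon list did so with the stricter filter and without Tumor replicate 1 or 5 or WT replicate 3 or 4. The mature regulatory dendritic cell list did so without WT replicates 3 and 5 or 3, 4 and 5, with pan-T scaling, and without Tumor replicate 5 or WT replicate 3 or 5 alone. No longer passing were helper T cytokines without WT replicates 1 and 2 or WT replicate 2 alone, oxidative phosphorylation without WT replicates 3 and 5 or WT replicate 5 alone, and proliferation with the stricter filter or pan-T scaling. Without WT replicates 3, 4 and 5, glycolysis, proliferation, ribosomal proteins and the unfolded protein response did not pass. Of the 21 lists, 16 passed upward without WT replicates 3, 4 and 5, and 20 or 21 under each other setting of camera with the preset correlation.

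Of the 65 named genes that were called, 27 (among them Ccr8, Tnfrsf9, Pdcd1, Penk, Il17a, Lyz2 and C1qa) were called in all 10 fits without 1 library, and none reversed in any. Of 22 named genes that were not called, 5 were called in some of those fits. Over all planned settings 1626 values of named genes kept their direction and side of the threshold, 279 lost the call, 48 gained it and 33 changed sign, all of them of genes not called (Apc, Gpr83, Adgre1, Mrc1, Krt8 and Lgals4). Apc, at 0.029, was -0.13, -0.14, -0.17, -0.13, -0.23, -0.070, -0.016, -0.19, -0.26 and -0.051 with RLE factors, upper-quartile factors, library size alone, DESeq2, stricter filter, 1 surrogate variable, protein coding genes only, WT replicates 3 and 5 left out, WT replicates 3, 4 and 5 left out and repeat-like genes left out, and -0.14 to 0.20 without each library. Gpr83 was -0.12, -0.017, -0.25, -0.19, -0.088 and -0.061 with upper-quartile factors, library size alone, limma voom with quality weights, stricter filter, WT replicates 1 and 2 left out and counts thinned, and -0.025 to 0.80 without each library. Adgre1, at 0.18, was -0.0057, -0.034, -0.0037, -0.26, -0.13 and -0.0081 with RLE factors, upper-quartile factors, DESeq2, limma voom with quality weights, stricter filter and WT replicates 3 and 5 left out, and -0.041 to 0.55 without each library. Mrc1, at 0.18, was -0.10, -0.0071, -0.087, -0.10, -0.19, -0.17 and -0.0026 with RLE factors, upper-quartile factors, library size alone, DESeq2, stricter filter, WT replicates 1 and 2 left out and counts thinned, and -0.44 to 0.80 without each library. Lrrc32 was -0.20 with background subtracted and -0.12 without WT replicates 1 and 2, where Lgals4 was 5.35 and Krt8 4.72, and these were 0.55 and 0.14 with quality weights. Pan-T scaling lowers every fold by construction and turned 22 genes: Prdm1 -0.31, Slc16a3 -0.79, Itgae -0.69, Klf2 -0.35, Cd69 -0.0043, Ikzf4 -0.98, Foxp3 -0.61, Cd4 -0.025, Ebi3 -0.94, Cd3e -0.98, Nrp1 -1.18, Izumo1r -0.80, Ikzf2 -0.93, Socs2 -1.78, Ptprc -0.48, Ctss -1.54, Cd83 -0.78, Lrrc32 -2.02, Gpr83 -2.99, Adgre1 -2.81, Mrc1 -2.78, Apc -3.25. With thinning added they were Prdm1 -0.27, Ccr6 -0.13, Slc16a3 -0.74, Itgae -0.72, Klf2 -0.21, Ikzf4 -1.06, Foxp3 -0.41, Cd4 -0.0013, Ebi3 -0.63, Cd3e -1.03, Nrp1 -1.20, Izumo1r -0.86, Ikzf2 -0.93, Socs2 -1.99, Ptprc -0.48, Ctss -1.56, Cd83 -0.74, Lrrc32 -2.04, Gpr83 -2.98, Adgre1 -2.59, Mrc1 -2.55, Apc -3.06. Depth limits the genes at few WT reads, such as Il17a and Ccr8, whose folds carry the error of those reads.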

Other observations

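The values in this part were chosen after the results were seen. After pan-T scaling 21 of the 293 higher genes stayed higher. Beyond those named in the comparison they included Spp1, encoding osteopontin (2.52 ± 1.17 log2 units, SE), the chemokine gene Cxcl2 (1.97 ± 0.79) and Aif1 (2.45 ± 1.15), all known from macrophages and picked from all genes tested, with an adjusted p that lies close to the unadjusted p. Klrg1, Cxcr6, Bcl2a1d (1.98 ± 0.84) and Gzma (1.98 ± 0.87) were among the 21 as well, and the cells that their reads came from were not tested. Of 23 genes higher under that scaling, 2 were not called on TMM: S100a8 (TMM 4.64 ± 1.20, adjusted p = 0.0595) and the hemoglobin gene Hba-a1 (6.06 ± 1.90, 0.141).

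Il17a reads came with few reads of the gamma delta T cell receptor: over the 5 Tumor libraries there were 2190 Il17a, 72 Trdc and 9463 Trac reads. Trdc and Trac are the constant segments of the delta and alpha chains. Of the Il17a reads 1201 were in Tumor replicate 4. Such sums do not tell which cells the Il17a reads came from, which was not tested.

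Transcription factors were not over-represented among the rises. Of 274 protein coding genes called higher, 13 carried a transcription factor family in the deposited table, against 1103 of 16773 tested (Fisher's exact test, 2-sided, odds ratio 0.704, p = 0.267). They included Prdm1, Gata3, Klf2 and Ikzf4, and 1 of the genes called lower carried such a family.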
